A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

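Poly(A)+ RNA was measured in 9 libraries of fission yeast, 3 each from the parental strain rpb1-CTD-T4A29 (T4A below) and from the suppressor mutants STF6 and STF9. Per the labels' protocols, RNA was purified with hot acid phenol from log phase cultures grown at 30 °C in YES medium, and libraries were made with a stranded poly(A)+ kit and sequenced as paired ends. Per the submitters' processing notes, the tools were HISAT2 2.1.0, SAMtools, HTSeq 0.10.0 and DESeq2, and the genome build was ASM294v2. The annotation, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here.

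The authors deposited a table of raw counts per gene for the 9 libraries, which are whole numbers with no normalization. They also deposited a table for each mutant against T4A, whose columns are per the file headers a log2 fold change with its standard error, a Wald score, a p-value with its adjusted form, and normalized counts averaged over each group, here treated as a signal. The overall mean normalized count was the same in both deposited tables for all 6986 genes used. For 2547 genes it lay outside the range of the 3 group means, so libraries not analysed here seem to have entered the authors' scaling or fit, which was not tested. Their tables are used below only for a comparison of calls.

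The count table held 6987 lines. One line (an all-zero duplicate of another ID) was dropped, leaving 6986, of which 384 had no count in any library. Systematic IDs were used as the table gives them, with the 4841 gene names the authors' tables pair with them, 2 of which stand there as numbers, in the way a spreadsheet turns names into dates, and are not used. RefSeq's annotation of ASM294v3 served only for synonyms and for which genes neighbour each other. It matched 5941 of the 5951 genes tested. Its build differs from the authors', so no coordinates are printed.

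Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (5951 genes), scaled by TMM, and fitted by glmQLFit to all 9 libraries with group as the only term, so that the 3 groups shared one estimate of the spread. Each comparison was tested by glmQLFTest, and p-values were adjusted by Benjamini-Hochberg over the 5951 genes. A gene is said to have risen or fallen where its adjusted p was under 0.05. Levels are counts scaled by TMM to a common library size (CPM) and are given as mean ± SD over the 3 libraries of a group. Folds are log2 ratios with their standard error (SE). The common biological coefficient of variation was 0.104.

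The 29 gene lists, the rule for the genes to name, the tests and their alternatives were fixed before the data were examined. The rule took, for each mutant against T4A, the 10 genes with the largest positive and the 10 with the largest negative fold among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries. For STF9 against STF6 it took the 5 largest each way, of which there were none. It added every member of the PHO lists and of a list of strain markers, and up to 4 members with the smallest p in each list. List members that are named because they alone did not pass or went the other way were chosen after their values were seen. Lists with at least 3 tested members (25) were tested against all other genes by camera in limma 3.58.1, with its preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the 25 lists. The same test with the correlation estimated from the data, and fry, were alternatives. fry asks whether the members of a list changed at all, a different question from camera's, which sets them against all other genes. With an estimated correlation none of the lists was called in any comparison.

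Alternatives were median-ratio scaling, library size alone, no filter on low counts, at least 1 CPM in all 9 libraries, DESeq2 1.42.0, a fit of only the 6 libraries compared, the replicate number as a block, an added 2-fold threshold, and leaving out each library in turn. The scripts were tested on simulated counts for the 5951 genes, 200 of them changed, with levels and spreads taken from the real data. For STF6 against T4A, 70.1% of the genes changed 1.5-fold were recovered, and 100% of those changed 2-fold or 4-fold. For STF9 against T4A these shares were 77.6%, 94.0% and 100%, and for STF9 against STF6 80.6%, 88.1% and 100%. There were 9, 7 and 10 false calls. A simulated list of shifted genes was called by camera in each comparison, and of 20 unshifted lists 1, 0 and 0 were called. Chance values for results that share the 3 control libraries came from 100 simulations of unchanged groups. All these simulations gave each gene the same spread in every group. They also drew genes independently of each other, so they do not test camera's false calls for lists with correlated members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

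Total counts ranged from 15374453 to 22909747 per library, and the median SE of a log2 fold was 0.12 in each comparison. All replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom from 3.19 to 9.70 within the mutants and from 24.4 to 91.6 within T4A. TMM factors ran from 0.859 in T4A replicate 2 to 1.09 in T4A replicate 3. The labels speak of replicate experiments without saying whether these were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. No batch or date was given in the sources used here.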

Results

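RNA levels were compared between a fission yeast strain with a Thr4 mutation in the carboxy-terminal domain (CTD) of the largest subunit of RNA polymerase II, rpb1-CTD-T4A29, and the mutants STF6 and STF9 derived as its suppressors. Per the series title, this CTD mutation over-represses the PHO regulon, the genes through which the cell takes up phosphate, and the suppressors bear on that repression. The genes mutated in STF6 and STF9 are not given in the sources used here. Each group had 3 libraries. Total counts were 20830106, 20274395 and 21910154 for T4A, 21324777, 22909747 and 15374453 for STF6, and 19250938, 17704108 and 19146574 for STF9. The first principal component, with 65.7% of the variance, separated the T4A libraries from all 6 mutant libraries, and T4A replicate 2 lay farthest out on it. Of the strain markers, ura4 was listed at 0 counts in all 9 libraries, which bounds its expected level at about 3 counts per library. Values for rpb1 were −0.29 ± 0.18 (log2 ± SE) in STF6 and −0.16 ± 0.18 in STF9 against T4A, and neither these nor those of leu1, ade6 and his3 passed the test.

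The first comparison asked which transcripts differ between STF6 and its parent. All 3 genes of the PHO regulon rose. The acid phosphatase gene pho1 (SPBP4G3.02) went from 109 ± 16.7 CPM (SD, n = 3) in T4A to 6046 ± 33.2 CPM in STF6, a 55.5-fold rise. The phosphate transporter gene pho84 (SPBC8E4.01c) went from 124 ± 12.4 to 2304 ± 49.8 CPM, 18.6-fold, and the glycerophosphodiester transporter gene tgp1 (SPBC1271.09) from 9.26 ± 2.83 to 245 ± 21.2 CPM, 26.8-fold. On the log2 scale these were 5.79 ± 0.14, 4.22 ± 0.11 and 4.74 ± 0.16 (SE), with adjusted p of 2.96e-11, 2.96e-11 and 5.75e-10 by edgeR's quasi-likelihood test. The list was called by camera (adjusted p = 4.37e-06; adjusted p = 0.188 with an estimated correlation), and 3 of 3 also rose when adjusted over the list alone. Because the strains are named as suppressors of PHO repression, the direction of these genes is not independent evidence.

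Other large increases in STF6 were in genes not on that list. SPBPB2B2.06c, a predicted extracellular 5'-nucleotidase gene, rose by 5.70 ± 0.32 and ecl3, a gene linked to chronological lifespan, by 5.33 ± 0.18. The T4A level of SPBPB2B2.06c was uneven, at 8.04 CPM in replicate 2 against 2.70 and 2.09 in replicates 1 and 3, so its fold depends on that library. Next came pma2 (a plasma membrane proton pump; 3.70 ± 0.27), guf1 (a mitochondrial elongation factor; 3.11 ± 0.25), SPCC11E10.01 (a predicted cystathionine beta-lyase; 2.70 ± 0.09), gpd3 (a glyceraldehyde 3-phosphate dehydrogenase; 2.61 ± 0.28) and spn5 (a meiotic septin; 2.36 ± 0.29). Their adjusted p ranged from 4.65e-10 for SPCC11E10.01 to 5.59e-05 for spn5. The folds of pma2, guf1 and spn5 rest on few counts. Levels went from 0.280 to 3.65 CPM for pma2, 0.528 to 4.68 CPM for guf1 and 0.812 to 4.41 CPM for spn5. SPBC1683.01, a predicted phosphate transporter gene chosen after its values were seen, rose from 61.2 ± 20.2 to 255 ± 6.67 CPM (2.06 ± 0.16). Of 5 other genes of phosphate handling, vtc4 (0.74 ± 0.08), pho8 and gde1 rose, pho7, which encodes the activator of the PHO genes, fell (−0.63 ± 0.10), and csk1 did not pass. This list was not called (adjusted p = 0.432).

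**Figure D1:**
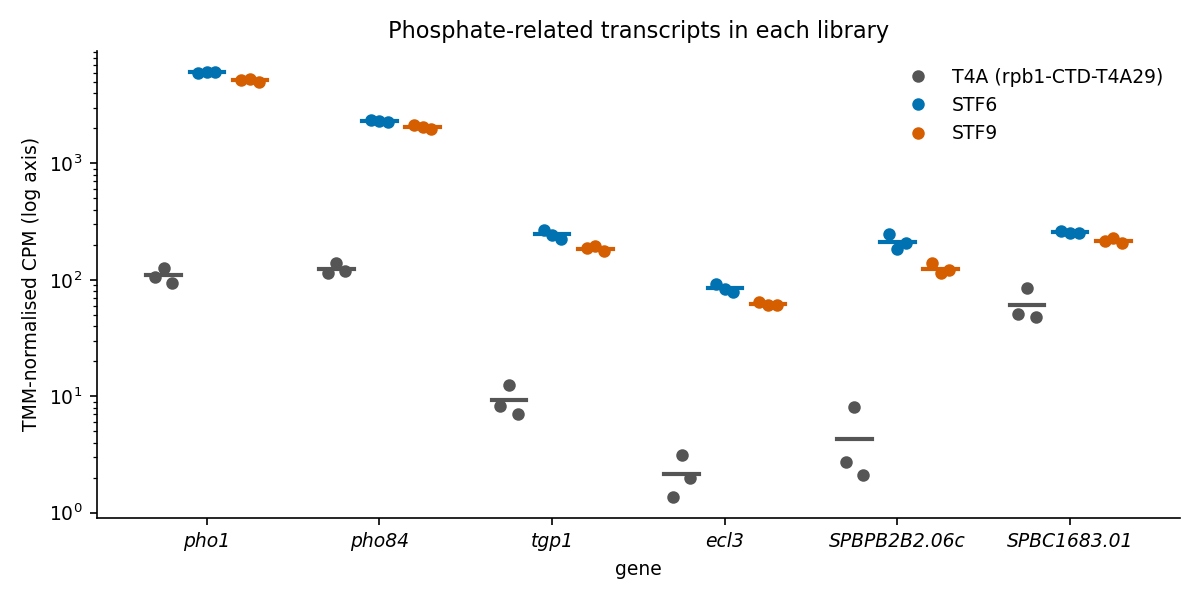
TMM-scaled CPM on a log axis for 6 genes, with 1 point per library and a bar at each group's mean (T4A grey, STF6 blue, STF9 orange). Besides pho1, pho84 and tgp1, ecl3 and SPBPB2B2.06c were taken for their large rises, and SPBC1683.01 after its values were seen. The title's term phosphate-related was not tested for ecl3 and SPBPB2B2.06c. For each gene all 6 mutant libraries lie above all 3 T4A libraries; pho1 averages 109 CPM in T4A, 6046 in STF6 and 5174 in STF9.

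The largest decrease in STF6 was in str1, a siderophore-iron transporter gene, from 144 ± 48.4 to 11.2 ± 0.454 CPM (−3.68 ± 0.22, adjusted p = 1.62e-07). Of 9 measured iron acquisition genes 7 fell (8 adjusted over the list alone), among them the ferric reductase gene frp1 (−2.17 ± 0.20), the multicopper oxidase gene fio1 (−2.06 ± 0.21) and the permease gene fip1 (−1.74 ± 0.19), and str2 and sib1 did not pass. The list was called (adjusted p = 4.58e-05; adjusted p = 0.490 with an estimated correlation). T4A replicate 2 had the highest mean log2 CPM over this list, 5.55, against 5.02 and 4.84 in the other T4A libraries and 3.55 to 3.81 in the 6 mutant libraries, and 6 of 9 fell without it.

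Heat shock and chaperone genes were lower in STF6, 11 of 12 measured (11 adjusted over the list alone), with ssa2 not passing. The Hsp70 gene ssa1 fell from 695 ± 188 to 122 ± 7.87 CPM (−2.51 ± 0.16), hsp16 from 1149 ± 73.1 to 331 ± 27.7 CPM (−1.80 ± 0.10), hsp104 by 1.50 ± 0.09 and hsp78 by 0.88 ± 0.10 on the log2 scale. Copies as similar as ssa1 and ssa2 can share reads, so their separate values are uncertain. The list was called (adjusted p = 4.46e-07; adjusted p = 0.188 with an estimated correlation). T4A replicate 2 was again highest, with a mean log2 CPM of 10.05 against 9.86 and 9.69 in the other T4A libraries and 8.86 to 8.91 in the mutants, and 11 of 12 fell without it. Of 10 genes of the oxidative stress regulator Pap1, 8 fell (8 adjusted over the list alone), led by the sulfiredoxin gene srx1 (−2.43 ± 0.17), the drug transporter gene caf5 (−1.93 ± 0.27) and gst2 (−1.62 ± 0.15), and tpx1 and trx2 did not pass. That list was called too (adjusted p = 3.74e-04; adjusted p = 0.490 with an estimated correlation). Leaving out T4A replicate 2, 7 fell and the list median went from −0.69 to −0.41. SPBPB21E7.04c, an O-methyltransferase gene, fell by 2.20 ± 0.26.

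Nuclear genes of the respiratory chain rose in STF6, 34 of 52 measured (34 adjusted over the list alone, with 1 lower), with qcr8 at 1.49 ± 0.09, cyt1 at 1.36 ± 0.09, qcr6 at 1.29 ± 0.11 and cox4 at 1.04 ± 0.08. The list's adjusted p was 1.89e-10 (adjusted p = 0.188 with an estimated correlation). Cytosolic ribosomal protein genes moved both ways, with 8 of 138 higher and 49 lower (9 and 50 adjusted over the list alone), a median of −0.22 and a list call (adjusted p = 4.21e-06; adjusted p = 0.797 with an estimated correlation). Over this list the T4A libraries spread more widely than the groups differed, from a mean log2 CPM of 9.74 in replicate 3 to 10.13 in replicate 2, against 9.75 to 9.83 in STF6. The counts followed single libraries, with 17 higher and 47 lower without T4A replicate 2, 96 lower without T4A replicate 3, 23 lower without T4A replicate 1 and 4 higher without STF6 replicate 1 or 2. Ribosome biogenesis genes were called upward (adjusted p = 0.0121; adjusted p = 0.797 with an estimated correlation), with 14 of 58 higher and 5 lower (11 and 5 adjusted over the list alone), fib1 leading at 1.02 ± 0.09. Without STF6 replicate 2 or 3, 4 of them rose, and without T4A replicate 3, 25.

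Among 947 non-coding RNAs tested, 251 fell and 72 rose in STF6 (244 and 70 adjusted over the list alone), and the list was called (adjusted p = 1.21e-05; adjusted p = 0.188 with an estimated correlation). Without STF6 replicate 3, 43 rose. Antisense RNAs made up 200 of those that fell. Since the strand setting of the counting is not given, values of antisense RNAs and their sense genes are uncertain. The antisense RNA of guf1, SPAC1B3.04c-antisense-2, fell by 2.87 ± 0.23 while guf1 itself rose. Others among the largest decreases were swi3-antisense-1 (−2.66 ± 0.25), SPCC1919.05-antisense-1 (−2.51 ± 0.14), rct1-antisense-1 (−2.47 ± 0.18), rex3-antisense-1 (−2.34 ± 0.24) and prp2-antisense-1 (−2.17 ± 0.25), whereas pof9-antisense-1 rose by 1.82 ± 0.11. Of these, swi3-antisense-1, rct1-antisense-1 and rex3-antisense-1 are annotated by the authors as possible alternative UTRs. Their reads may therefore belong to another gene's transcript. The lncRNAs that flank the PHO genes were not analysed here. In RefSeq's annotation of ASM294v3 the nearest upstream gene on the same strand is the lncRNA nc-pho1 for pho1, prt2 for pho84 and nc-tgp1 for tgp1, and none of these was among the features counted. The list meant for them matched only prt1, an unrelated predicted transcription factor gene (−0.10 ± 0.11, not passing).

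The inositol pyrophosphate kinase gene asp1 rose from 22.6 ± 1.38 to 45.7 ± 1.03 CPM in STF6 (1.02 ± 0.10, adjusted p = 7.66e-06) and the pyrophosphate hydrolase gene aps1 by 0.84 ± 0.12. Of 5 measured genes of this metabolism 4 rose and ipk1 fell (−0.49 ± 0.12), with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.0562). Genes of 3' end processing and termination included 8 of 21 higher and 2 lower (8 and 2 adjusted over the list alone). Cleavage and polyadenylation factor genes cft2 (0.98 ± 0.12), pfs2 (0.91 ± 0.13) and swd22 (0.58 ± 0.08) rose, as did the termination factor gene rhn1 (0.82 ± 0.13). The list did not pass (adjusted p = 0.0772).

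In all, 1141 genes rose and 1145 fell in STF6, of which 142 and 195 changed at least 2-fold, and in 50.3% of the 5951 genes the libraries of the groups did not overlap, where chance gives 10%. The number higher depended on each STF6 library, and was 753, 754 and 745 without replicates 1, 2 and 3. Without T4A replicate 2 or STF6 replicate 3 the list of 3' processing genes passed (adjusted p = 0.0429 and 0.0498), as did the inositol pyrophosphate list (adjusted p = 0.0429 and 0.0359). The histone list also passed without T4A replicate 2 (adjusted p = 0.00580). With an estimated correlation in the fit of all libraries, the adjusted p of these lists were 0.490, 0.371 and 0.797.

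**Figure D2:**
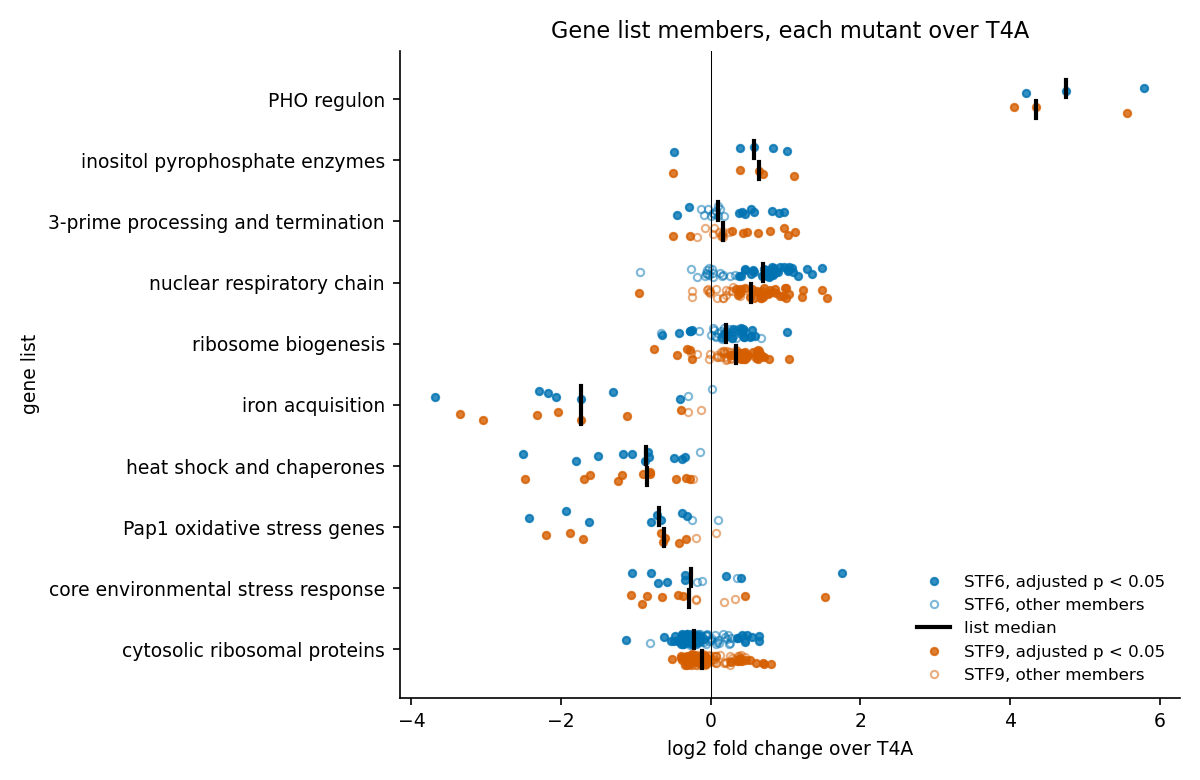
Log2 fold change over T4A of each tested member of 10 gene lists, for STF6 (blue) and STF9 (orange); filled points passed the test, open points did not, and bars mark list medians. The 3 PHO genes lie above 4 in both mutants, 7 of 9 iron acquisition genes and 11 of 12 heat shock genes fell in each, and ribosomal protein genes lie on both sides of 0.

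The same question was asked of STF9. Here too all 3 PHO genes rose. The level of pho1 was 5174 ± 171 CPM (SD, n = 3), 47.5-fold above T4A (5.57 ± 0.14, adjusted p = 4.45e-11). That of pho84 was 2057 ± 96.3 CPM, 16.6-fold above (4.05 ± 0.11, adjusted p = 4.45e-11), and that of tgp1 was 185 ± 9.19 CPM, 20.3-fold above (4.34 ± 0.16, adjusted p = 1.65e-09). The list was called (adjusted p = 1.76e-05; adjusted p = 0.218 with an estimated correlation), 3 of 3 also adjusted over the list alone, with the same limit on its direction as for STF6.

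Outside that list SPBPB2B2.06c (4.93 ± 0.32), ecl3 (4.88 ± 0.18), pma2 (3.52 ± 0.28), guf1 (3.01 ± 0.26) and SPCC11E10.01 (2.70 ± 0.09) rose, followed by ngl1, a peptide N-glycanase gene (2.46 ± 0.23), and SPBC1703.08c, a predicted folate cyclo-ligase gene (2.38 ± 0.24). For SPBPB2B2.06c the uneven T4A level, highest in replicate 2 at 8.04 CPM, applies here too. gpd3 was at 2.26 ± 0.28 and spn5 at 2.17 ± 0.29. Few counts again lay behind pma2 (0.280 to 3.24 CPM), guf1 (0.528 to 4.34) and spn5 (0.812 to 3.84). Levels of ngl1 (1.40 to 7.55 CPM) and SPBC1703.08c (0.942 to 4.97) were also low. SPBC1683.01 rose to 216 ± 9.78 CPM (1.83 ± 0.16). Of the 5 other phosphate genes vtc4, pho8 and gde1 rose, pho7 fell (−0.64 ± 0.10), and csk1 did not pass (list adjusted p = 0.399).

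Iron acquisition genes fell in STF9, 7 of 9 (8 adjusted over the list alone; adjusted p = 2.97e-05; adjusted p = 0.400 with an estimated correlation), with str1 at −3.35 ± 0.21, frp1 at −2.32 ± 0.21, fio1 at −2.05 ± 0.21 and fip1 at −1.74 ± 0.19. Without T4A replicate 2, the T4A library with the highest levels of this list, 6 of 9 fell. Heat shock genes fell in 11 of 12 cases, ssa2 excepted, also without that library (11 adjusted over the list alone; adjusted p = 7.48e-07; adjusted p = 0.218 with an estimated correlation). Levels in STF9 were 124 ± 10.3 CPM for ssa1 (−2.48 ± 0.16) and 357 ± 43.2 CPM for hsp16 (−1.69 ± 0.10), with hsp104 at −1.61 ± 0.09 and hsp78 at −0.80 ± 0.10. Of the Pap1 list 8 of 10 fell (8 adjusted over the list alone; adjusted p = 7.16e-04; adjusted p = 0.496 with an estimated correlation), with srx1 at −2.20 ± 0.17, caf5 at −1.88 ± 0.27 and gst2 at −1.71 ± 0.15. When T4A replicate 2 was left out, 7 fell and the median went from −0.62 to −0.39. SPBPB21E7.04c fell by 2.45 ± 0.27.

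Respiratory chain genes rose in STF9, 32 of 52 with 1 lower (34 and 1 adjusted over the list alone; adjusted p = 3.98e-09; adjusted p = 0.218 with an estimated correlation), with qcr8 at 1.56 ± 0.09, qcr6 at 1.49 ± 0.11, cyt1 at 1.23 ± 0.09 and cox4 at 0.96 ± 0.08. Ribosome biogenesis genes were higher in 25 of 58 cases and lower in 5 (29 and 5 adjusted over the list alone; adjusted p = 0.00108; adjusted p = 0.703 with an estimated correlation), with fib1 at 1.05 ± 0.09, and 10 rose without STF9 replicate 2. Of 138 ribosomal protein genes 12 rose and 26 fell (7 and 6 adjusted over the list alone), with a median of −0.11. Without T4A replicate 2 the excess of decreases was gone, with 22 higher, 21 lower and a median of −0.04, while 74 fell without T4A replicate 3, 6 fell without T4A replicate 1 or STF9 replicate 3, and 6 rose without STF9 replicate 2. Their list call (adjusted p = 0.0114; adjusted p = 0.834 with an estimated correlation) was lost without T4A replicate 2 (adjusted p = 0.536), the T4A library with the highest levels of this list.

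Non-coding RNAs fell in 252 of 947 cases and rose in 70 (227 and 57 adjusted over the list alone; adjusted p = 2.97e-05; adjusted p = 0.218 with an estimated correlation), 190 of those that fell being antisense RNAs, with the same uncertainty of strand. The largest decreases were in rct1-antisense-1 (−2.72 ± 0.19), rex3-antisense-1 (−2.72 ± 0.25), swi3-antisense-1 (−2.63 ± 0.25), SPAC1B3.04c-antisense-2 (−2.59 ± 0.22) and SPCC1919.05-antisense-1 (−2.40 ± 0.14). Here too rct1-antisense-1, rex3-antisense-1 and swi3-antisense-1 are possible alternative UTRs by their annotation. asp1 rose to 48.8 ± 3.22 CPM (1.11 ± 0.10) and aps1 by 0.70 ± 0.12, in a list of 5 with 4 higher and ipk1 lower that was not called (adjusted p = 0.0615). Genes of 3' end processing and termination were called upward, 8 of 21 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0297; adjusted p = 0.400 with an estimated correlation), with cft2 at 1.13 ± 0.12, pfs2 at 1.03 ± 0.13, rhn1 at 0.98 ± 0.13 and swd22 at 0.43 ± 0.08. That call was lost without T4A replicate 3 (adjusted p = 0.0718) or STF9 replicate 1 (adjusted p = 0.0505).

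In STF9 1368 genes rose and 1265 fell, of which 141 and 190 changed at least 2-fold, and libraries did not overlap in 54.0% of genes. The number higher was 807 without STF9 replicate 2 and 843 without replicate 3, and the number lower 814 without replicate 3.

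The mutants were then compared with each other. The 3 PHO genes averaged lower in STF9 than in STF6, by log2 values of −0.22 ± 0.11 for pho1, −0.16 ± 0.09 for pho84 and −0.40 ± 0.13 for tgp1. For each gene all 3 STF9 libraries lay below all 3 STF6 libraries. Libraries of the mutants did not overlap in 1011 of the 5951 genes, and genes of 1 regulon are not independent, so this separation is weak evidence. None passed the test singly (adjusted p = 0.980 for each; tgp1 passed when adjusted over the list alone), while as a list they were called lower (adjusted p = 0.0113; adjusted p = 0.988 with an estimated correlation). Ribosomal protein genes were called higher in STF9 as a list, with a median of 0.09 and 128 of 138 values above 0 (adjusted p = 6.18e-08; adjusted p = 0.988 with an estimated correlation). No member passed singly, also when adjusted over the list alone. No single gene was called by edgeR in the fit of all 9 libraries, with 178 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.674. DESeq2 called 1 gene lower in STF9 and 0 higher, with 169 at an unadjusted p under 0.05. That gene was tlh2, a subtelomeric helicase gene chosen after its values were seen, at 4.62 ± 0.970 CPM in STF6, 0.740 ± 0.129 in STF9 and 2.59 ± 1.94 in T4A. It has near-identical copies, so its value is uncertain.

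A fit of only the 6 mutant libraries, in which the wider spread of T4A plays no part, called 10 genes lower and 7 higher in STF9. Genes named from it were chosen after their values were seen. Lower were pho1 (−0.22 ± 0.04, adjusted p = 0.00862), tgp1 (−0.40 ± 0.06, adjusted p = 7.35e-04), ecl3 (−0.45 ± 0.07), SPBPB2B2.06c (−0.77 ± 0.08), SPBC1683.01 (−0.24 ± 0.05), tlh2 (−2.61 ± 0.24), cox24, gfh1 and the uracil-related genes urg1 (−0.60 ± 0.06) and urg2 (−0.51 ± 0.05). Higher were the ribosomal protein genes rps1002 (0.23 ± 0.04), rpl44 (0.21 ± 0.04) and rpp203, the translation factor gene tif5, btf3, yhb1 and SPAC27D7.11c. Leaving out T4A replicate 2 from the fit of all libraries gave 6 genes lower, including tgp1 (adjusted p = 0.00122), and leaving out T4A replicate 3 gave 1. Without T4A replicate 3 or without STF9 replicate 1, 4 lists rather than 2 were called.

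Both mutants changed largely the same genes against T4A. Of the genes called in each, 980 rose and 1034 fell in both, and 0 moved in opposite directions. Independent lists of these sizes would share 262 and 243, while simulated unchanged groups against 3 controls simulated with them shared 0. Such groups hold almost no called genes, so this 0 is no chance value for the shared counts. Across the 5951 genes the log2 folds correlated with r = 0.941, against a mean of 0.494 (0.447 to 0.532) in the simulations, and genes are not independent replicates. The covariance was 0.273 against 0.0156 simulated, a difference of 0.257. The simulations gave each gene the same spread in every group, whereas the real T4A libraries differed more among themselves. Within T4A the chi-square per degree of freedom ran from 24.4 to 91.6, against 3.19 to 9.70 within the mutants. The simulated r and covariance are therefore likely too low and are no fair chance values for these data. The 3 T4A libraries cannot be split into parts of at least 2, so part of the excess may come from these shared controls.

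**Figure D3:**
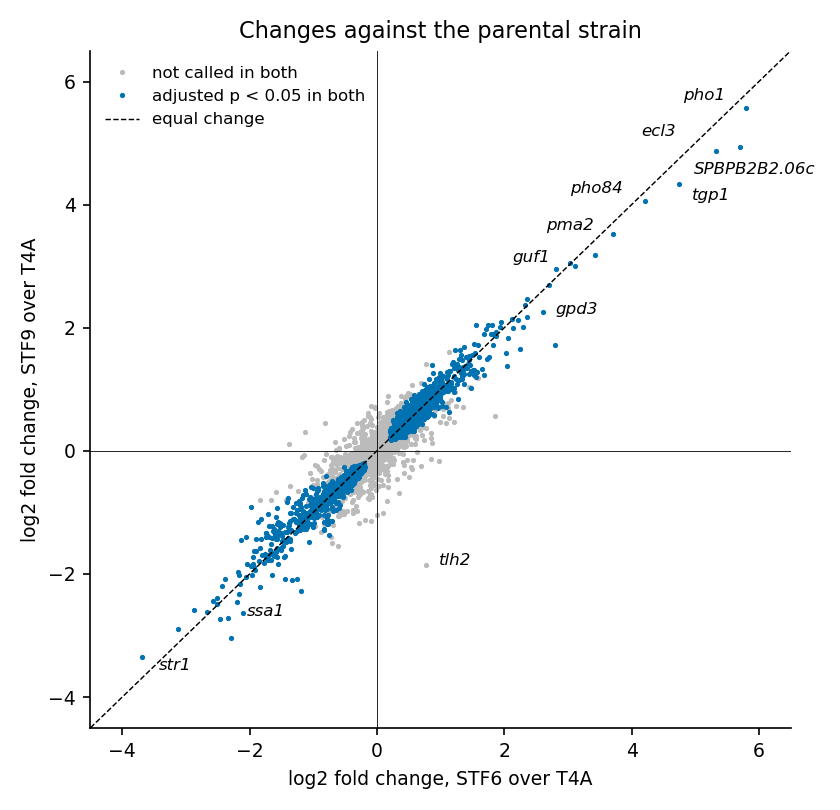
Log2 fold change over T4A in STF6 (x axis) and in STF9 (y axis) for 5951 genes; blue points passed the test in both mutants, and the dashed line marks equal change. The blue points run along the line, with r = 0.941 over all genes, and pho1 lies highest in both mutants.

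Compared with these calls, the authors' deposited tables list 1309 genes higher and 1590 lower in STF6, and 1524 higher and 1711 lower in STF9, at the same threshold. Of the genes called here, 2255 of 2286 in STF6 and 2592 of 2633 in STF9 were also called in the authors' deposited tables, all in the same direction. In the authors' deposited tables pho1 stands at a log2 fold of 5.75 in STF6 and 5.52 in STF9, pho84 at 4.18 and 4.01, and tgp1 at 4.69 and 4.28.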

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

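Of the tests in this part, the one on library scaling was chosen only after the result was seen. Both results below drew attention because STF9 and STF6 differed in a direct test of one against the other while each was set against the same parent. The PHO regulon was lower in STF9 as a list (adjusted p = 0.0113 by camera), by −0.22, −0.16 and −0.40 for pho1, pho84 and tgp1, lower in 3 of 3 STF9 libraries for each gene. Libraries of the mutants were also apart, in either direction, in 1011 of the 5951 genes. Cytosolic ribosomal protein genes were higher in STF9 as a list (adjusted p = 6.18e-08), with a median log2 difference of 0.09. With an estimated correlation both adjusted p were 0.988, and by fry, which asks whether members changed at all rather than more than other genes, 0.993. The real grouping called 2 lists and 6 of the 10 splits of the 6 libraries gave as many, the highest other split giving 4. With 10 splits no share under 0.05 can be reached. Every other split mixed the mutants unevenly and kept part of any difference between them, so its list calls are no chance value.

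For the ribosomal protein genes, weighed further, the list's median lay 0.0791 above that of all genes with library size alone and 0.0782 above it with TMM, and as 1 factor per library moves all genes alike and cancels in this difference, it cannot by construction be its source, while a bias that varies with expression level was not tested. STF9 replicate 3 had the highest mean log2 CPM over the list, 9.94 against 9.88 in both other STF9 libraries, yet without it the median was 0.0771 against 0.0857 with it. The mean ran from 9.75 to 9.83 in the STF6 libraries. A small difference in growth state between the cultures stays open and was not tested, as does the difference between the mutants themselves. As the members share their noise, the loss of the call with an estimated correlation leaves the difference as a hypothesis.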

How the results depend on the processing

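All alternatives were set beforehand, but the genes named from the fit of 6 libraries were chosen only after the result was seen. Which direction held more called genes depended on the setting. In STF9 there were 1368 higher and 1265 lower with TMM, but 1247 and 1352 with median-ratio scaling and 1318 and 1373 with DESeq2. Library size alone (1044 and 1115) also reversed this balance, as did some fits without 1 library. The balance was kept without a filter (1384 and 1238), with at least 1 CPM and with the replicate block. The folds of pho1, pho84 and tgp1 against T4A kept their direction and passed under every alternative run. Without each library in turn they ran for pho1 from 5.70 to 5.92 (STF6) and 5.47 to 5.70 (STF9), for pho84 from 4.16 to 4.31 and 4.0 to 4.14, and for tgp1 from 4.58 to 5.01 and 4.17 to 4.61. In STF9 against STF6 they ran from −0.25 to −0.20, −0.20 to −0.13 and −0.45 to −0.35, tgp1 passing without T4A replicate 2. Counts of genes ran from 745 to 1410 higher and 905 to 1443 lower in STF6, 807 to 1645 and 814 to 1528 in STF9, 0 to 0 and 0 to 6 in STF9 against STF6, and 1516 to 2564 shared. Lists called ran from 8 to 11, 8 to 9 and 2 to 4, and the correlation from 0.917 to 0.949. Fewer samples were tested in each of these fits. The lowest counts of genes higher came without a mutant library (745 without STF6 replicate 3, 807 without STF9 replicate 2).

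A 2-fold threshold left 142 higher and 195 lower in STF6, 141 and 190 in STF9, and 272 shared, by its construction. With only the 6 libraries compared, fewer genes were called against T4A. There were 874 higher and 850 lower in STF6 and 927 and 992 in STF9. Shared genes numbered 1467, against 2014 in the fit of all 9 libraries. STF9 against STF6 had 7 higher and 10 lower in this setting, with pho1 (−0.22, adjusted p = 0.00862) and tgp1 (−0.40, adjusted p = 7.35e-04) now passing. In that comparison the T4A libraries, which differ more among themselves, are left out of the spread. DESeq2 called 1 lower there. With an estimated correlation 0, 0 and 0 lists were called for STF6, STF9 and STF9 against STF6, and fry called 0 in the last. Without a filter the correlation was 0.788; genes with very few counts then enter. The causes of other moves were not tested.

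Same-numbered libraries deviated from their group means with correlations from −0.31 to 0.38, and other-numbered ones with correlations from −0.36 to 0.39. No pairing by replicate number was thus evident, though these values cannot exclude it. With the replicate number as a block, 1260 genes were higher and 1172 lower in STF6, 1504 and 1299 in STF9, and 0 and 0 in STF9 against STF6, with 8, 10 and 3 lists. Library size alone moved the median fold of all genes by 0.06, 0.05 and −0.01. Of other named genes' folds under settings other than leaving out 1 library, 31 lost and 15 gained a call and 2309 did neither. For list tests these numbers were 24, 16 and 335. Leaving out each library in turn, they were 86, 21 and 2971 for the named genes' folds and 3, 13 and 659 for list tests. In the simulations some changes of 1.5-fold were missed. The simulations held 200 changed genes and the same spread in every group, and depth was not varied, so recovery in the real data may be lower. In the fit of all 9 libraries tlh2, at −2.62 in STF9 against STF6, was not called.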

Other observations

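Among the tests in this part, the correlation of sense genes with their antisense RNAs (both uses of it) and the list of glycolytic genes were chosen only after the result was seen. Several gene groups not described above held called members without a list call in either mutant under the planned test (adjusted p from 0.0550 to 0.890). Their counts of called members are small and many depended on single libraries. Of 12 core environmental stress genes 6 fell in each mutant, among them the trehalose synthase gene tps1 (−1.05 in STF6, −1.06 in STF9), ntp1 and hsp9, while 3 rose in STF6 and 2 in STF9, led by rds1, a ferritin-related gene (1.76 and 1.52). Without T4A replicate 2, 4 rose in each mutant, and 1 rose in STF6 without T4A replicate 3 or any 1 STF6 library and in STF9 without STF9 replicate 2. Of 7 glucose-repressed genes 4 fell in STF6 and 5 in STF9, such as the transporter gene ght3 (−1.36 and −1.46), whereas the malic enzyme gene mae2 rose (1.25 and 1.08). In STF9 that list (adjusted p = 0.0550) was called with the replicate number as a block (adjusted p = 0.0365), with library size alone (0.0425) and without T4A replicate 3 (0.0274), so its call depends on the setting. By fry, which asks whether members changed at all rather than more than other genes, its adjusted p was 0.0409. By camera with an estimated correlation it was 0.712. Of 12 nitrogen permease and starvation genes isp4, an oligopeptide transporter gene, rose (2.22 and 2.13), and 5 fell in STF6 and 4 in STF9, but without T4A replicate 2, 3 rose and 4 fell in STF6 and 3 rose and 3 fell in STF9. Of 7 sterol and hypoxia genes erg32 rose in both and 4 fell in STF6 and 5 in STF9 (3 without STF9 replicate 2 and 2 without replicate 3), and their list was called with library size alone (adjusted p = 0.0266 and 0.0350). With TMM and an estimated correlation the list's adjusted p were 0.797 and 0.834. Of 3 galactose genes gal10 fell (−1.55 and −1.84). The rise of gal7 in STF6 was lost without any 1 of 7 libraries, T4A replicate 2 among them, and is not counted here as a change.

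Markers of other cell states were not called as lists under the planned test. Of 15 mating and nitrogen starvation genes 4 rose and 4 fell in STF6 and 2 and 4 in STF9 (without T4A replicate 2, 2 fell in each and 4 rose in STF9; without STF6 replicate 1, and in STF9 without STF9 replicate 2 or 3, 1 fell), with map1, a mating-type regulator gene, at 1.46 and 1.39; the list's pheromone genes mfm1, mfm2 and mfm3 are near-identical copies and uncertain. Of 16 meiotic genes 3 rose and 2 fell in each mutant (1 fell without T4A replicate 2). Histone genes, also near-identical, rose in 3 of 9 cases in STF6 and 1 in STF9, but in 6 and 4 without T4A replicate 2 and in 1 in STF6 without STF6 replicate 1. Without T4A replicate 2 their list was called in STF6 (adjusted p = 0.00580), as it was with library size alone (0.0103). In the fit of all libraries its adjusted p in STF6 was 0.797 with an estimated correlation and 0.132 by fry. MBF genes of the G1-S transition rose in 2 of 7 and fell in 1 in each, and rose in 4 in STF6 and 3 in STF9 without T4A replicate 2. In STF6 1 rose without any 1 of 6 libraries (T4A replicate 1, each STF6 library, and STF9 replicates 1 and 2). By fry, with its different question, their list was called in both mutants (adjusted p = 0.0202 and 0.0185). Of 7 thiamine genes 1 fell, of 3 zinc genes 1 rose and 2 fell, and of 3 copper genes ctr6 fell in both and ctr4 rose in STF9. The rises among zinc and copper genes were lost without any 1 of at least 7 libraries. Of 49 amino acid synthesis genes 8 rose and 13 fell in STF6 and 8 rose and 15 fell in STF9. Without T4A replicate 2 there was no such excess of decreases, with 16 rising and 14 falling in STF6 and 14 and 15 in STF9, whereas 21 fell in each without T4A replicate 3 and 7 in STF9 without STF9 replicate 3. Neither of 2 Tf2 retrotransposons passed. tlh2 fell in STF9 (−1.85), as the only tested member of its list, and none of 36 mitochondrially encoded genes had enough counts to be tested. A list of 15 glycolytic genes drawn up after gpd3 was seen had 6 higher in STF6 and 6 higher with 1 lower in STF9 (unadjusted camera p = 0.0658 and 0.155; p = 0.612 and 0.693 with an estimated correlation).

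The decrease of non-coding RNAs was weighed against technical sources. Low counts are not likely to be its cause, since the median log2 fold of the non-coding RNAs, −0.18 over both mutants, lay below all 1000 of 1000 draws of other genes matched on expression (−0.02 to 0.11). The smallest matching bin held only 30 other genes, drawn with replacement, so the range of the draws may be too narrow. Genomic DNA or stray RNA in the T4A libraries would lower intergenic RNAs as much as antisense ones, yet intergenic RNAs lay 0.219 higher (95% bootstrap interval 0.119 to 0.307). Sense reads counted on antisense features would tie each antisense RNA to its sense gene, and rho across 504 pairs was −0.165. Some antisense RNAs are annotated as possible alternative UTRs, and whether reads of other genes' transcripts account for the decrease was not tested. A hypothesis that also stays open is that antisense RNAs themselves are fewer in the mutants, which the design cannot separate from other consequences of the mutations.

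The same pairs bear on a hypothesis that a sense gene and its antisense RNA change in opposite directions, as guf1 and SPAC1B3.04c-antisense-2 did. That example has few counts, with guf1 at 0.528 CPM in T4A and the antisense RNA at 0.710 CPM in STF6. The negative rho of −0.165 was beyond chance pairing (two-sided permutation p = 3e-04 over 10000 shuffles), at −0.106 in STF6 and −0.216 in STF9, and Pearson's r was −0.180. Pairs are not independent replicates. In terms of calls, where the antisense RNA fell in both mutants 41 of 151 sense genes rose in both, against 78 of 353 elsewhere (Fisher's exact test, p = 0.252). In the same pairs 8 of 151 sense genes fell in both, against 41 of 353 elsewhere, a difference that was not tested. The relation may be weak and spread over many pairs.

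The decrease of heat shock genes in both mutants was weighed against T4A replicate 2, which lay apart. It is not likely the source alone, because 11 of 12 members fell in both mutants without it and all 3 T4A libraries lay above all mutant libraries in the list's mean. A difference of culture or library batch cannot be told apart from the groups, as 0 libraries carry a batch label. Lower stress in the suppressed strains stays open as an untested biological explanation.

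As the PHO genes have a lncRNA as their nearest upstream neighbour, a hypothesis was that other protein-coding genes that rose at least 2-fold in both mutants do too. In RefSeq's annotation of ASM294v3, 46 of 83 such genes (55.4%, PHO genes left out) had a lncRNA as the nearest upstream gene on the same strand, against 48.5% of other coding genes. The one-sided permutation p, within strata of expression, was 0.150, so the data leave this undecided. Of 59 coding genes at least 2-fold lower in both, 54.2% had one. SPBPB2B2.06c, ecl3, pma2 and guf1, picked from the genes with the largest rises, all had one. They are among the 83 genes already tested, so they add no evidence.

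Other splits of the libraries were fitted for each result. For STF6 against T4A the real grouping called 2286 genes and the highest other split 0, so 1 of 10 splits was as large, and for STF9 against T4A 2633 and 0, again 1 of 10. For STF9 against STF6 all 10 of 10 splits gave 0 genes, as the real one did. Lists called were 8 for STF6, with 7 of 10 splits as large and up to 12, and 9 for STF9, with 7 of 10 and up to 13. Every other split mixed the groups unevenly and kept part of the real difference, so its list calls are no chance value. Splits of 6 libraries are too few for a share under 0.05. For the genes shared by both mutants 1 of 100 splits of the 9 libraries was as large, the real one with 2014, and the highest other split gave 2003. That split was 1 of 5 that kept the T4A libraries together, while the 94 that parted them gave 0. Among those 5 the overlap ran from 0 to 2003. A large overlap thus arose only where the T4A libraries were kept together, though not in every such split. Kept together here means under any 1 label, so they could also stand as a mutant group against mutant libraries as the control. Only 1 comparison then holds the T4A libraries, and a small overlap follows by construction. How many of the 5 were of this kind is not given. As 2014 and 2003 hardly differ, the share does not test whether STF6 and STF9 share a response.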
